A study of Mus musculus with 2 samples.

How the data were processed

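The series holds total RNA sequencing of heart tissue from 2 female B6CASTF1/J mice aged 2 months, 1 library per animal. The labels number the animals as separate biological replicates of 1 group (n = 2), name the mm10 assembly, ribosomal RNA reduction and ERCC spike-ins, and give 300 ng as the starting amount. The aligner, the tools' versions and their filters are not given in the sources used here.

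For each library there is 1 gene table, with 81881 entries, and 2 transcript tables. The expected counts of the gene table and of the first transcript table are estimated reads per feature, not normalised, and in the layout of RSEM per the file headers, which give an effective length 99 bases below the length; the deposited readme derives them from transcriptome alignments and names the M21 annotation. The TPM of these tables was computed by the authors over all entries of a table, spike-ins included, per the file headers. The second transcript table holds estimated counts and TPM in the layout of kallisto per the file headers, quantified from a read file per the deposited readme, with an effective length 326 or 327 bases below the length of long transcripts. It lists 141864 transcripts, all of them also in the first table. The gene table also gives the posterior standard deviation of each count, a spread of read assignment within 1 library, which is called the assignment spread here.

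Gene names, types and coordinates came from the GENCODE M21 annotation of mm10, matched on identifiers (55536 genes). Entries with a number in place of a gene identifier (26248 entries) held 4 reads in animal 1 (9.5e-06% of all reads) and 2 in animal 2 (4.8e-06%) and stayed out of library sizes and tests. Gene reads were 41862417 and 41790009, and total reads with spike-ins 42113557 and 42050214. The limit that a count of 0 allows, 3 reads, was 0.0717 and 0.0718 CPM of gene reads. Reads carry no molecular identifiers, so intervals and limits cover counting error only.

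With 1 group no comparison of groups was made. Levels were described as mean and SD of the deposited TPM over both animals. For the comparison of animals the expected counts were rounded to whole numbers and genes with at least 20 reads in total were kept (16133 genes). Library sizes were scaled by TMM, the trimmed mean of M values, in edgeR 4.0.16 (R 4.3.3), and the biological coefficient of variation was estimated by its dispersion fit with an intercept alone, which leaves 1 degree of freedom per gene and pools over genes. Each gene's reads were compared by a two-sided exact binomial test given the scaled library sizes, with Benjamini-Hochberg adjustment at 0.05 and a minimum of 2-fold. It compares 2 libraries, not conditions, and sees counting error alone, so it also picks up ordinary variation between animals. Intervals of ratios are exact 95% intervals of the same binomial share, and log2 ratios used a prior count of 0.5. The 2 libraries are not copies of each other: with no fold minimum 1798 genes differed beyond counting error.

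Gene lists, 41 with 452 members, were fixed before the data were examined: sarcomere, calcium handling and ion channels, atrial, ventricular, fetal and wall stress, cardiac transcription factors, mitochondrially encoded, nuclear oxidative phosphorylation, fatty acid oxidation, glycolysis, energy transfer and oxygen store, fibroblast, endothelial, mural, macrophage, lymphocyte, neutrophil, erythroid, platelet, adipocyte, brown adipocyte, Schwann cell and nerve, mesothelial, skeletal muscle, lung epithelium, liver, thymocyte, cartilage and valve, immediate early, heat shock, circadian clock, fasting and glucocorticoid, interferon, hypoxia, proliferation, replication-dependent histones, long and small non-coding RNA, imprinted, X inactivation and escape, Y-linked, and splicing regulators. The median log2 ratio of each list with at least 3 measured genes was placed among 10000 random lists of the same size matched on mean level in 40 bins. Some genes belong to more than 1 list.

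Genes were named by a rule fixed with the lists: the 20 nuclear protein-coding and the 10 non-coding genes with the highest mean TPM, up to 4 members per list by level and up to 4 by ratio in shifted lists, the 12 protein-coding and 3 other genes with the largest ratio in each direction among differing genes at 1 TPM or more, the 3 lowest and 3 highest major transcript shares among 28 isoform genes, and the 8 genes with the largest difference between quantifications. Of the genes that this rule names for their transcript share, 1 is not reported here. Members of lists that passed the 2-fold test outside this rule (Myh1), Nr1d1 in the clock list and genes marked so in the closing part were chosen after their values were seen. Genes with an assignment spread above 10% of their reads, globin genes and near-identical copies are reported as uncertain. Whether counting used strand is not given in the sources used here, so overlapping genes on opposite strands may share reads. Both animals carry CAST alleles while reads were assigned to an mm10 annotation.

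The major transcript share is the share of a gene's transcript TPM in its highest transcript, over those genes with at least 10 TPM for which it was measured. Both quantifications were compared as sums of transcript TPM per gene, over genes with at least 1 TPM.

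The comparison was tested on simulated data drawn from the real means and library sizes with 200 changed genes. With a variation of 0.08 between libraries, 93% of changes of 1.5 and 100% of changes of 3 on the log2 scale were recovered over 16098 genes, and 41 unchanged genes passed 2-fold and 3651 with no fold minimum. With counting error alone 84% and 98% were recovered over 16142 genes, and 0 unchanged genes passed 2-fold and 9 with no fold minimum. The pooled coefficient of variation is raised by changed genes: a simulated 0.08 was estimated at 0.0808 with no changed genes and at 0.143 with 200, and counting error alone with 200 changed genes at 0.125. Of 100 random lists 4 fell outside the central 95% with a variation of 0.08, and 7 of 100 with counting error alone.

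Alternatives tried were DESeq2 1.42.0 size factors, total counts and spike-in totals in place of TMM, other count and TPM filters, other fold minimums, another pseudocount, the second quantification, shares of reads in place of TPM, leaving out the mitochondrially encoded genes, leaving out each animal, and, chosen after seeing the data, an assignment spread below 10% of the reads in both libraries and total counts for the coefficient of variation. Other computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.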

Results

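Total RNA from heart tissue was sequenced in 2 female mice of the B6CASTF1/J strain, a hybrid of C57BL/6 and CAST parents, at an age of 2 months. Both animals belong to 1 group (n = 2), each with 1 library made from 300 ng of RNA after reduction of ribosomal RNA and addition of ERCC spike-ins, a set of synthetic transcripts of known amount. Libraries held 41862417 gene reads in animal 1 and 41790009 in animal 2. With no other group to set against, the data describe the heart transcriptome, how far 2 animals of 1 kind differ, which transcript each gene used, and how far levels depend on the quantification. Levels are TPM, the length-corrected relative abundance of transcripts, given as mean ± SD over the 2 animals. Over 16133 genes with at least 20 reads the median log2 TPM ratio of animal 2 over animal 1 was 0.22. The SDs include this shift of scale, so a small or large SD does not by itself show how alike the animals were. Coordinates are those of the mm10 assembly with the GENCODE M21 annotation.

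Contractile genes led the nuclear protein-coding transcriptome together with globin genes. The 21 sarcomere genes summed to 44099.9 ± 4549.6 TPM (SD, n = 2), with a median of 783 TPM per gene. Myh6 (ENSMUSG00000040752.16; chromosome 14, 54941921 to 54966927), which encodes the fast alpha myosin heavy chain of adult mouse heart, reached 7986 ± 543 TPM, against 806 ± 62.9 TPM for Myh7 (chromosome 14, 54970684 to 54994626), the slow beta chain encoded next to it. In the second quantification they were at 7562 and 1713 TPM. The ventricular light chain gene Myl2 (chromosome 5, 122100951 to 122113472) stood at 7650.3 ± 872 TPM, cardiac alpha actin Actc1 (chromosome 2, 114047282 to 114053548) at 4446 ± 716 TPM and cardiac troponin I gene Tnni3 (chromosome 7, 4518305 to 4524229) at 4021 ± 429.8 TPM. Of the other sarcomere genes among the 20 highest, Tpm1 reached 4015 ± 511 TPM, Myl3 3843 ± 366 TPM, Tnnt2 3413 ± 329 TPM and Tnnc1 2058 ± 252 TPM.

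Calcium cycling genes were also abundant. The list of 21 calcium handling and ion channel genes summed to 9297 ± 798 TPM, led by the sarcoplasmic reticulum pump Atp2a2 (chromosome 5, 122453513 to 122502225) at 4836 ± 498 TPM and its inhibitor Pln (chromosome 10, 53337667 to 53345987) at 2395 ± 101 TPM. The release channel Ryr2 stood at 371 ± 20.5 TPM and the calcium-binding Hrc at 352 ± 38.1 TPM. Cardiac transcription factors were present at far lower levels, 536 ± 71.1 TPM over 16 genes, with Esrra at 62.1 ± 9.10 TPM, Mef2a at 57.0 ± 7.25 TPM, Ppargc1a at 52.3 ± 16.7 TPM and Mef2d at 49.0 ± 3.90 TPM. The 11 splicing regulators summed to 678 ± 91.2 TPM, led by Qk at 207 ± 26.5 TPM, and included Mbnl2 at 88.1 ± 12.9 TPM, Mbnl1 at 84.9 ± 13.8 TPM and the titin splicing regulator Rbm20 at 77.8 ± 10.3 TPM.

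Markers of both chambers were detected. The 4 ventricular genes summed to 11505 ± 1240 TPM, nearly all of it from Myl2 and Myl3 (22979 TPM in the second quantification, with Myl2 at 17011 TPM), while the ventricular transcription factors Irx4 and Hey2 stood at 10.8 ± 1.24 and 1.47 ± 0.255 TPM. The 10 atrial genes summed to 1177 ± 117 TPM. Among them were the natriuretic peptide gene Nppa at 587 ± 61.3 TPM, the atrial light chains Myl4 at 231 ± 25.2 TPM and Myl7 at 221 ± 24.4 TPM, and sarcolipin, Sln, at 30.4 ± 5.87 TPM. The 8 genes of the fetal and wall stress list, which includes Myh7 and Nppa, summed to 1922 ± 119 TPM, with Ankrd1 at 153 ± 22.1 TPM, skeletal alpha actin Acta1 at 116 ± 18.8 TPM and Nppb at 80.0 ± 50.04 TPM.

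Mitochondrial and metabolic genes took a large share of the measured RNA. Genes of the mitochondrial genome, ribosomal RNA included, made up 28.2% ± 0.850 of all TPM (27.6% in animal 1 and 28.8% in animal 2), of which the 2 ribosomal RNAs were 15.7% ± 0.0562. The direction between animals turned on other scales: 27.4% and 25.6% of reads, 36.3% and 33.2% of TPM in the second quantification, and a ratio of scaled reads of 0.883. Pseudogenes of mitochondrial genes on chromosome 1 (6 genes) took a further 6.63% of TPM and 3.08% of reads. The 13 mitochondrially encoded protein genes summed to 124168 ± 8870 TPM, led by mt-Co1 at 32890 ± 2846 TPM, mt-Co3 at 16505 ± 959 TPM, mt-Atp6 at 14375 ± 1111 TPM and mt-Cytb at 13736 ± 1061 TPM. In the second quantification mt-Atp6 stood above mt-Co3, at 30295 against 14839 TPM, so the level of mt-Atp6 and its rank are uncertain. Nuclear genes of oxidative phosphorylation (22 genes) summed to 19380.1 ± 1921 TPM, with the ATP synthase subunits Atp5b at 3192 ± 268 TPM and Atp5a1 at 1570 ± 174 TPM, and Cox4i1 at 1688 ± 171 TPM. The 18 fatty acid oxidation genes summed to 8382 ± 1018 TPM and included the fatty acid carrier Fabp3 at 2234 ± 302 TPM, Hadhb at 806 ± 92.3 TPM, the uptake receptor Cd36 at 681 ± 72.3 TPM and Acaa2 at 519 ± 58.8 TPM. The 15 glycolysis genes summed to 6904 ± 814 TPM, with Gapdh at 1616 ± 214 TPM, Aldoa at 1420 ± 183 TPM and Ldhb at 1124 ± 123 TPM. In the second quantification their sum was 11039 TPM, with Gapdh at 3649 and Ldhb at 2164 TPM. Myoglobin, Mb (chromosome 15, 77015487 to 77050670), the oxygen store of muscle, reached 7352.5 ± 635 TPM, and with the creatine kinases Ckm (1412 ± 168 TPM) and Ckmt2 (929 ± 86.1 TPM), the ADP carrier Slc25a4 (1809 ± 167 TPM) and Ak1 gave 11753 ± 1079 TPM for the 5 genes of energy transfer and oxygen storage.

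Blood contributed to the profile. The 8 erythroid genes summed to 47586 ± 6104 TPM, and the alpha and beta globin genes alone were 4.78% ± 0.617 of all TPM, with Hbb-bs at 16967 ± 1607 TPM. In the second quantification the erythroid sum was 77137 TPM and the globin share 7.76%. Levels of the single globin genes are uncertain, since their near-identical copies share reads. The 4 platelet genes summed to 63.2 ± 2.60 TPM, with Pf4 at 28.9 ± 3.44 TPM and Ppbp at 25.9 ± 1.42 TPM. Neutrophil genes were near the detection limit, with 80 reads in animal 1 and 82 in animal 2 over 6 genes and a sum of 1.92 ± 0.170 TPM. The 11 lymphocyte genes summed to 12.4 ± 6.26 TPM (7.97 TPM in animal 1 and 16.8 TPM in animal 2), mostly immunoglobulin chains, with Ighm at 4.94 ± 2.43 TPM and Igkc at 3.88 ± 3.03 TPM.

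Non-myocyte markers of the heart wall were lower than the myocyte genes. The 12 endothelial genes summed to 711 ± 139 TPM, with Fabp4 at 234 ± 36.8 TPM, the water channel Aqp1 at 138 ± 38.7 TPM and Pecam1 at 44.4 ± 7.99 TPM. The 11 fibroblast genes summed to 531 ± 87.4 TPM, with the matrix genes Mgp at 177 ± 18.2 TPM, Dcn at 151 ± 25.6 TPM and Col3a1 at 68.3 ± 17.1 TPM. The 10 mural genes, markers of pericytes and smooth muscle, summed to 345 ± 72.1 TPM, led by Rgs5 at 116 ± 25.6 TPM, and the 11 macrophage genes summed to 106 ± 24.2 TPM, led by the complement genes C1qb at 20.2 ± 4.22 TPM and C1qa at 19.7 ± 3.83 TPM. The 6 mesothelial genes summed to 20.1 ± 0.544 TPM, with Upk3b at 7.21 ± 0.219 TPM. Schwann cell and nerve genes (7 genes) summed to 5.27 ± 0.587 TPM, and cartilage and valve genes (5 genes) to 3.75 ± 0.368 TPM, mostly Comp at 2.38 ± 0.0141 TPM. Fat markers were low and uneven, at 41.5 ± 25.9 TPM over the 6 adipocyte genes (23.2 TPM in animal 1 and 59.8 TPM in animal 2) and 23.0 ± 4.21 TPM over the 4 brown adipocyte genes, of which Cidea gave 18.5 ± 2.496 TPM.

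**Figure D1:**
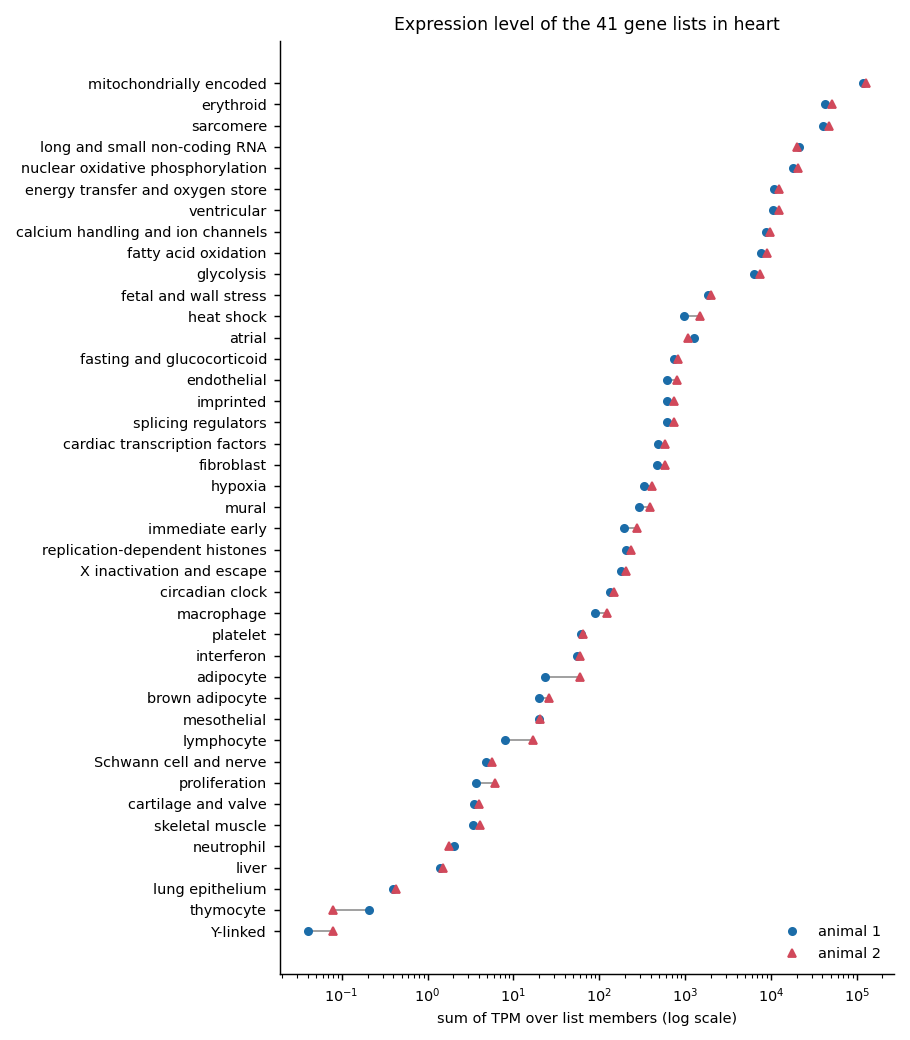
Summed TPM of each gene list on a log axis, with 1 point per animal. The mitochondrially encoded list (124168 TPM), the erythroid list (47586 TPM) and the sarcomere list (44099.9 TPM) were the highest, and the Y-linked list (0.060 TPM) the lowest.

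Genes of lung, liver, thymus and skeletal muscle were close to absent. Lung epithelium genes (7 genes) held 12 reads in animal 1 and 9 in animal 2, a sum of 0.415 ± 0.0212 TPM. The 6 liver genes summed to 1.46 ± 0.0636 TPM, and the thymocyte genes held 12 and 6 reads (0.145 ± 0.0919 TPM). Skeletal muscle genes (10 genes) summed to 3.71 ± 0.495 TPM, led by Tnni2 at 1.23 ± 0.156 TPM. The 7 Y-linked genes held 3 and 4 reads (0.060 ± 0.0283 TPM). Xist, the long RNA that coats the inactive X chromosome (chromosome X, 103460366 to 103483254), stood at 20.7 ± 1.17 TPM with 11064 and 9815 reads, and the 7 genes of the X inactivation and escape list summed to 191 ± 17.3 TPM.

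Among regulated programmes, heat shock genes were the most abundant, at 1243 ± 364 TPM over 9 genes, with the constitutive chaperones Hspa8 at 556 ± 180 TPM and Hspa5 at 271 ± 84.6 TPM. The 14 fasting and glucocorticoid genes summed to 784 ± 65.2 TPM, led by Pdk4, which restrains glucose oxidation, at 288 ± 13.5 TPM. Hypoxia genes (7 genes) summed to 372 ± 52.5 TPM, with Vegfa at 128 ± 23.0 TPM, and the 21 immediate early genes to 236 ± 59.7 TPM, with Ccn2 at 37.2 ± 14.4 TPM. The 16 circadian clock genes summed to 142 ± 9.98 TPM, with Tef at 22.9 ± 3.36 TPM and Per1 at 18.99 ± 0.771 TPM. The 13 interferon genes summed to 57.9 ± 3.02 TPM and the 9 proliferation genes to 4.88 ± 1.67 TPM, with Mki67 at 0.620 ± 0.297 TPM. Replication-dependent histone genes (12 genes) gave 220.3 ± 23.8 TPM, led by Hist1h4h at 87.8 ± 7.67 TPM. The 27 imprinted genes summed to 679 ± 81.5 TPM, of which Gnas gave 456 ± 63.6 TPM and Igf2 26.2 ± 0.304 TPM.

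In all, 12022 genes reached at least 1 TPM in both animals, 11023 of them protein-coding, with 12233 genes in animal 1 and 12544 in animal 2. The 10 highest genes took 45.5% ± 4.98 of all TPM (49.0% in animal 1 and 41.998% in animal 2). Highest among non-coding genes were mt-Rnr2 at 100850 ± 936 TPM, the near-identical 7SL RNA genes Rn7s1 and Rn7s2, mt-Rnr1 at 54636 ± 238 TPM and Rn7sk at 14983 ± 169 TPM. The 7SL RNA, the scaffold of the signal recognition particle, was 17.3% ± 5.87 of all TPM over both genes. It was 2.95% of reads, and 2.2e-04% of TPM in the second quantification. Gm26917 (5854 ± 837 TPM) and Gm42418 (1509 ± 474 TPM), annotated at the ribosomal DNA on chromosome 17, followed with Rpph1 (2921 ± 613 TPM), the RNA of ribonuclease P, Malat1 (1635 ± 81.5 TPM) and Rmrp (851 ± 11.8 TPM; 5693 and 5220 reads). The level of Rmrp is uncertain, since a second gene of this name annotated inside it took 4458 and 4222 reads. The list of 17 long and small non-coding RNAs summed to 20597.7 ± 852 TPM, against 1152 TPM in the second quantification.

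The 2 animals were alike across genes. Over 12398 genes with a mean of at least 1 TPM, log2(TPM + 1) had a Pearson correlation of 0.987 and a Spearman correlation of 0.985 across genes, which are not independent replicates. Of 4456 protein-coding genes with at least 2000 reads, 95.9% lay within 1.2-fold, with a robust SD of 0.08 in log2 ratio. The pooled biological coefficient of variation was 0.0829, which is not shown to be variation between animals alone: data simulated with 200 changed genes and counting error as the only noise gave 0.125. In contractile genes the ratio between animals was near 1: none of the 21 sarcomere genes and none of the 21 calcium handling genes passed the 2-fold test described next, over all genes or adjusted over the list alone.

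A small set of genes differed between the animals, with Cyp26b1 and the adipocyte and heat shock lists higher in animal 2 and small non-coding RNAs higher in animal 1. Cyp26b1 (ENSMUSG00000063415.12; chromosome 6, 84571414 to 84593908), an enzyme that degrades retinoic acid, had 145 reads in animal 1 and 1078 in animal 2, a 7.03-fold difference (95% interval 5.92 to 8.44; adjusted p = 3.05e-163, exact binomial test). Slpi (chromosome 2, 164354070 to 164389095), a secreted protease inhibitor, was 4.89-fold higher in animal 2 (3.56 to 6.98; 44 and 229 reads), and the lipoxygenase gene Alox15 (chromosome 11, 70344152 to 70352031) 4.602-fold (3.70 to 5.82; 95 and 463 reads). The inducible chaperones Hspa1b (3.88-fold, 3.15 to 4.86) and Hspa1a (3.49-fold, 2.83 to 4.36), neighbours on chromosome 17, and Pck1 (chromosome 2, 173153048 to 173159273), which encodes phosphoenolpyruvate carboxykinase (2.76-fold, 2.40 to 3.19; 261 and 761 reads), were higher in animal 2 as well. Hspa1a and Hspa1b are near-identical copies, so how their reads were shared between them is uncertain.

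In total 210 of 16133 genes with at least 20 reads differed at least 2-fold, 72 higher in animal 2 (56 protein-coding) and 138 higher in animal 1 (34 protein-coding). The test was the two-sided exact binomial test of reads with Benjamini-Hochberg adjustment; it compares 2 libraries and not conditions, and with 1 library per animal it has no replicate check. Scaled by total counts, with no correction for composition, 103 genes were higher in animal 2 and 126 in animal 1. In data simulated over 16098 genes with a variation of 0.08 between libraries and 200 changed genes, 41 unchanged genes passed. With no fold minimum 3651 unchanged genes passed, more than the 1798 genes called in the real data. The simulated data thus varied more than the real ones, and their false calls do not estimate those among the 210. Many calls rest on reads shared with other copies: 100 of the 210 genes had an assignment spread below 10% of their reads in both libraries (38 higher in animal 2 and 62 in animal 1), and among protein-coding genes 37 were higher in animal 2 and 11 in animal 1. Of these 11, all low in reads (88 at most over both animals), Hamp2, a gene of the hepcidin family, had 32 and 13 reads (2.54-fold higher in animal 1) and Fam228b 52 and 24 reads (2.26-fold). With no count filter Hamp2 did not pass (adjusted p = 0.057, exact binomial test).

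The remaining protein-coding genes named by the fixed rule are uncertain, since their spread of read assignment exceeded 10% of their reads. Higher in animal 2 among these were Hist2h2aa1 (0 and 50 reads), Gm28038 (0 and 26), Gm20503 (10 and 99), Gm28635 (105 and 399), Zc3h11a (190 and 710 reads, at the copy on chromosome 1, 133619871 to 133661380) and Hist1h2bn (9 and 28). Higher in animal 1 were Zfp969 (89 and 10 reads), Mrpl23 (163 and 26), Hist1h4n (56 and 18), Dynlt1c (83 and 39), Gm2564 (51 and 24), Tgtp2 (88 and 43), Gm14440 (552 and 285) and Gm20390 (186 and 97). In the second quantification Hist2h2aa1, Gm20503 and Zc3h11a lay on the other side of 0, at log2 ratios of -0.04, -0.52 and -0.086, and Gm28635, Mrpl23, Hist1h4n, Dynlt1c, Gm2564, Tgtp2 and Gm20390 did not pass. The non-coding genes with the largest ratios, Gm6565 (0 and 57 reads), Gm24497 (5 and 554) and Gm2274 (0 and 43) in animal 2 and Gm14760 (112 and 0), Gm12671 (69 and 0) and Rnu3b4 (61 and 0, for 1 of 2 genes of this name) in animal 1, had an assignment spread above their whole read count, so no fold is given, and Gm2274 turned to a log2 ratio of -0.46 in the second quantification.

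**Figure D2:**
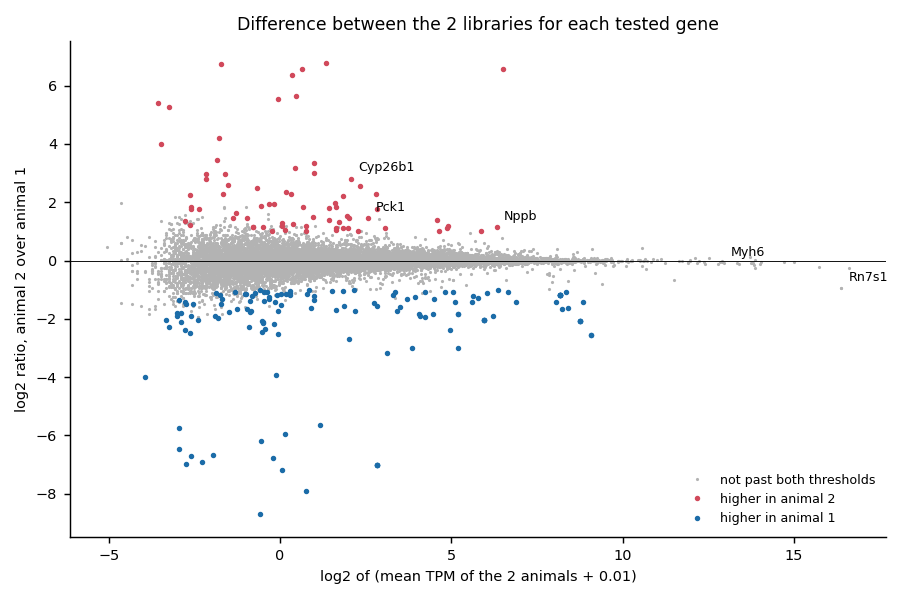
Log2 ratio of animal 2 over animal 1 for each gene with at least 20 reads, against the log2 of its mean TPM with a small constant added, with the 210 genes that differ at least 2-fold in colour. Most genes lie near 0, Cyp26b1 has a log2 ratio of 2.81 and Nppb of 1.14, and Rn7s1 (log2 ratio -0.94) is at the right.

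Small non-coding RNAs were 52 of the 138 genes higher in animal 1, or 25 of 62 with an assignment spread below 10%. Of 100 such genes with at least 20 reads, 93 had a ratio below 1 in animal 2 and 52 were at least 2-fold higher in animal 1, against 1 higher in animal 2. With an assignment spread below 10% of the reads 67 genes were left, with a median log2 ratio of -0.78, 64 below 0 and 25 at least 2-fold higher in animal 1. In the second quantification 3 of the 100 had at least 20 reads, and none passed. Over all 3527 annotated small non-coding RNA genes the summed scaled reads in animal 2 were 0.546 of those in animal 1. Most of these reads were 7SL RNA, and without it the ratio was 0.723. By class it was 0.313 for small nuclear, 0.505 for small nucleolar and 0.835 for small Cajal body RNAs. Small nuclear RNAs had the lowest median log2 ratio (-1.52 over 26 genes, 25 of them at least 2-fold higher in animal 1), followed by small nucleolar RNAs (-1.06 over 49 genes, 23 at least 2-fold higher in animal 1). Many are near-identical copies with equal counts: the 26 small nuclear RNA genes had 15 different pairs of counts, and 8 of them a spread below 10%, so these gene numbers overstate the separate differences. The small Cajal body RNAs stood at -0.17 over 9 genes, 3 of them at least 2-fold higher in animal 1, each with a spread below 10%. The 7SL genes together fell from 21.5% to 13.2% of TPM between animal 1 and animal 2 (log2 ratio of reads -0.94 for each of Rn7s1 and Rn7s2), Rpph1 was 1.58-fold higher in animal 1 (1.55 to 1.61) and Rn7sk 1.19-fold. All small non-coding RNAs together were 24.9% of TPM in animal 1 and 15.8% in animal 2. Their share of reads was far lower, 4.30% and 2.48%, and in the second quantification they were 0.052% and 0.048% of TPM. The median log2 TPM ratio of the 16133 genes was 0.22, and ratios between the animals are given from reads scaled by the trimmed mean of M values.

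**Figure D3:**
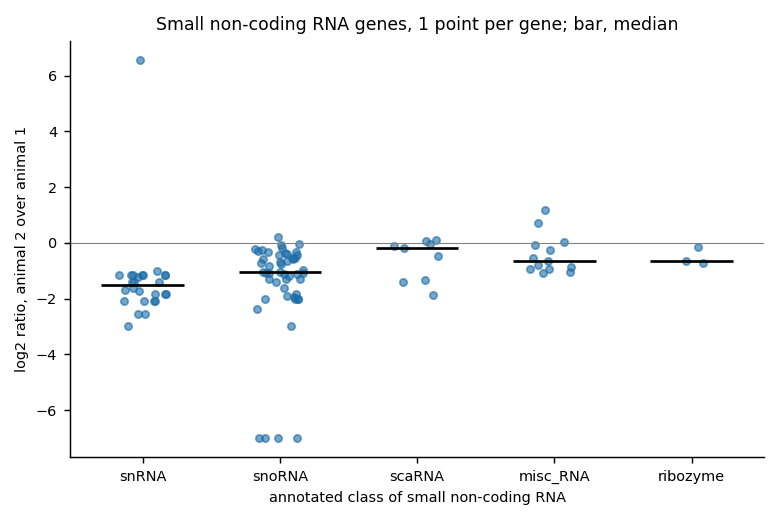
Log2 ratio of animal 2 over animal 1 for 100 small non-coding RNA genes, by class, with 1 point per gene. Medians were -1.52 for small nuclear RNAs, -1.06 for small nucleolar RNAs and -0.17 for small Cajal body RNAs.

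Fat, stress and stromal lists were shifted towards animal 2. The 5 measured adipocyte genes had a median log2 ratio of 1.2, above every one of 10000 random lists of the same size and level, and 3 passed the 2-fold test (3 adjusted over the list alone): Adipoq (2.73-fold, 2.08 to 3.67; 68 and 197 reads), Cidec (2.49-fold; 72 and 190 reads) and the complement factor Cfd (2.30-fold; 486 and 1180 reads). The brown adipocyte list had a median of 0.57, from Ucp1 (158 and 249 reads), Dio2 (83 and 130) and Cidea (632 and 688), with none past 2-fold. All 9 heat shock genes had ratios above 1 (median log2 ratio 0.40), and 2 passed the 2-fold test, Hspa1b and Hspa1a (2 adjusted over the list alone). Among immediate early genes 17 of 20 had ratios above 1 (median 0.24), and 2 passed (2 adjusted over the list alone), the stress-induced factor Atf3 (2.16-fold; 139 and 317 reads) and the nuclear receptor Nr4a3 (2.00-fold; 182 and 385 reads). In the lymphocyte list (median 0.37 over 8 genes) Igkc passed, with 28 and 87 reads (1 adjusted over the list alone), but not in the second quantification, where its log2 ratio was 0.75. Nr4a3, at the 2-fold limit, no longer passed when genes were filtered at 200 reads (log2 ratio 0.998).

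Markers of several non-myocyte types were moderately higher in animal 2, none by 2-fold. Median log2 ratios were 0.25 for mural genes (10 of 10 above 0), 0.24 for fibroblast genes (8 of 11), 0.20 for macrophage genes (10 of 11) and 0.17 for endothelial genes (11 of 12). Examples are Myh11 (1.43-fold), Col1a1 (1.27-fold), Lyve1 (1.41-fold) and Aqp1 (1.27-fold). With no fold minimum, 6 mural, 7 fibroblast, 5 macrophage and 9 endothelial genes passed the exact binomial test as higher in animal 2 over all genes (8, 8, 6 and 9 adjusted over the list alone), and 1 fibroblast gene passed as higher in animal 1 over the list alone. Passing with no fold minimum says little of a list, since 1798 of 16133 genes did so. In the simulation 3651 unchanged genes among 16098 did so, though the simulated data varied more than the real ones. Hypoxia genes had a median of 0.13, with Vegfa at 1.19-fold. In the fetal and wall stress list the median was 0.08 over members that went both ways: the natriuretic peptide gene Nppb passed the 2-fold test (2.20-fold higher in animal 2, 2.06 to 2.37; 1129 and 2625 reads; 1 adjusted over the list alone), while its neighbour Nppa was 1.36-fold higher in animal 1 (1.33 to 1.39).

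Atrial genes went the other way. Of 10 atrial genes 1 had a ratio above 1, the median log2 ratio was -0.35 and 9 genes were higher in animal 1 with no fold minimum (9 adjusted over the list alone), among them Sln (1.54-fold, 1.43 to 1.67), Myl7 (1.37-fold, 1.31 to 1.44) and Myl4 (1.35-fold, 1.30 to 1.40). None reached 2-fold, and the same limit of the test with no fold minimum applies. The ventricular list was centred at 0.01. Median log2 ratios below those of random lists were also found for long and small non-coding RNA (-0.25), interferon genes (-0.21, with Ifit1 at 81 and 48 reads), X inactivation and escape genes (-0.19, with Xist 1.19-fold higher in animal 1), mitochondrially encoded genes (-0.10, 13 of 13 below 0) and circadian clock genes (-0.07 over 7 genes above 0 and 9 below, with Tef 1.30-fold higher in animal 1 and Nr1d1 1.30-fold higher in animal 2). In the mitochondrial list mt-Co2 is uncertain, as its reads are shared with copies on chromosome 1. The other members are not shown to be free of such sharing.

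Of 36 lists with at least 3 measured genes, 17 lay outside the central 95% of random lists, 11 towards animal 2 and 6 towards animal 1, where 1.8 would be expected by chance if genes of a list were independent. These percentiles describe 2 libraries. Of the other lists, Myh1 in the skeletal muscle list (22 and 1 reads) and Hist2h2aa1 in the histone list passed the 2-fold test (1 in each adjusted over the list alone), and no member of another list did. On the log2(TPM + 1) scale, where the median of all genes is 0.17, the brown adipocyte, interferon and hypoxia lists fell back inside the range of random lists, and the proliferation list (median 0.17 on reads) moved outside it. In the second quantification the clock list was inside the range and the proliferation list outside, at 0.31.

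Transcript use was mixed in many genes. Among 4811 measured genes with at least 10 TPM the major transcript held a median of 65.4% ± 0.6997 of the gene's TPM. In 1363 of them (28.3%) it held less than 50% and in 1075 (22.3%) more than 90%. These shares do not cover all expressed genes. With the limit at 1 TPM 10628 genes were measured, against 12398 genes with a mean of at least 1 TPM. Of 28 genes known for alternative splicing or for cardiac isoforms 27 were measured, 13 with a major transcript under 50%. Among the lowest shares were those of the adaptor Sorbs2 (Sorbs2-220, 24.4% ± 0.187) and the transcription factor Mef2c (Mef2c-212, 24.6% ± 1.21), which in the second quantification held 13.3% ± 0.484 and 15.4% ± 3.23, below Sorbs2-208 and Mef2c-201. The highest were those of the Z-disc protein Actn2 (Actn2-201, 95.1% ± 2.26), tropomyosin Tpm1 (Tpm1-205, 96.6% ± 0.542) and the light chain Myl3 (Myl3-201, 99.5% ± 0.145). Both animals had the same major transcript in 4238 of 4517 genes (93.8%), and both quantifications in 3544 of 4745 (74.7%) and in 20 of the 27 listed genes. In some genes the share differed more between quantifications than between animals: in the second one Tpm1-205 held 70.9% ± 0.112 and Myl3-201 69.4% ± 0.231.

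Levels depended on the quantification, most of all those of short RNAs. Small non-coding RNAs took 20.4% of TPM in the first quantification and 0.050% in the second. As TPM is a relative abundance, levels of other genes are therefore not on the same scale in both. Over 13268 genes at 1 TPM or more, gene levels of both quantifications had a Spearman correlation of 0.894 across genes, or 0.974 for protein-coding genes alone. They differed more than 4-fold in both animals for 760 genes, 416 lower and 344 higher in the second quantification. Under 200 bases of transcript length 135 of 174 genes were more than 4-fold lower in the second quantification and 0 more than 4-fold higher, and from 200 to 400 bases 137 and 21 of 232. Rn7sk, the regulator of transcription elongation, was at 14983 TPM in the first and at 0 in the second, mt-Atp8 at 3829 TPM and 0, and Rmrp at 851 TPM and 0. Rn7s1 and Rn7s2 were each at 85942 ± 29158 TPM in the first and 1.101 ± 0.941 TPM in the second. The pseudogenes Gm10925 (14593 TPM in the first) and Gm28439 (847 ± 196 TPM in the second) on chromosome 1 are copies of mitochondrial sequence, and the pseudogene Gm12338 was at 1458 TPM and 0, so these 3 are uncertain.

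**Figure D4:**
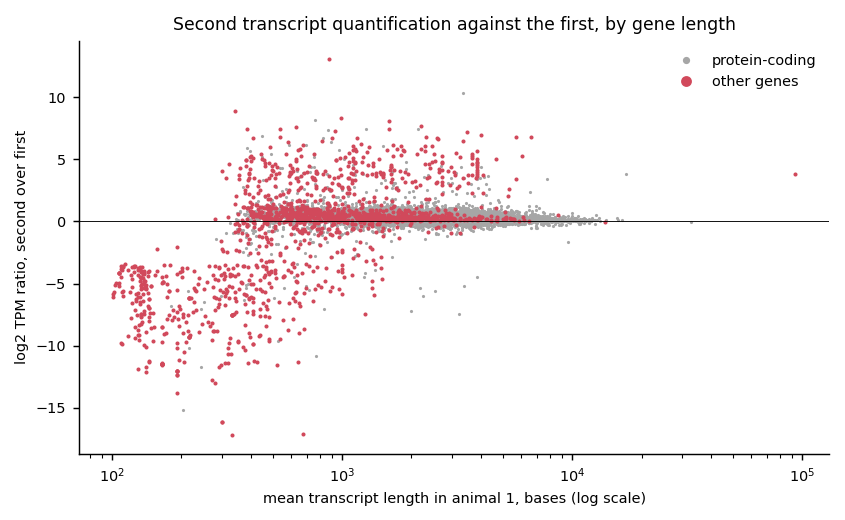
Log2 ratio of gene level in the second over the first quantification against transcript length, with 1 point per gene. The median was -5.94 under 200 bases and 0.23 at 2000 bases or more.

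Spike-ins were recovered at close but not equal shares in both libraries. They took 0.596% of reads in animal 1 (95% exact Clopper-Pearson interval 0.594 to 0.599) and 0.619% in animal 2 (0.616 to 0.621), with 70 and 75 of 96 spike-ins detected. Over 47 spike-ins with at least 20 reads the Pearson correlation of log2 reads was 0.999. Their log2 ratios, scaled on each library's spike-in total, had a median of -0.003 and a robust SD of 0.12. That scaling sets the centre near 0, so the median does not compare spike-ins with genes.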

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

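No test in this part was chosen after its result was seen. Among the entries with a number in place of a gene identifier, which no comparison uses, 4 reads fell in animal 1, above the 3 reads that a count of 0 allows, and 2 fell in animal 2. No control samples exist to set this against, and what these entries stand for is not given in the sources used here. Rules for outlying samples and for differences between groups need at least 4 samples or 2 groups and were not run.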

How the results depend on the processing

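The restriction to genes with an assignment spread below 10% of their reads and total counts for the coefficient of variation were chosen only after the data were seen. No paired analysis was possible because there is 1 group. Leaving out an animal gives no correlation, coefficient of variation, differing genes or list shift, since 1 library is left, and for means it gives the other animal's value, which with 2 animals always lies within 1 SD. Without animal 1 or animal 2, detected genes rose from 12022 to 12544 or 12233. Genes over 4-fold between quantifications rose from 760 to 827 or 881. Genes with a measured transcript share went both ways, from 4811 to 5062 or 4539. The causes below were not tested unless the alternative's own construction shows them.

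At 5 TPM 7603 genes were detected, by construction fewer. The mitochondrial share was 26.5% of reads and 34.7% of TPM in the second quantification, and the 10 highest genes took 33.3% of reads. The correlation of the animals was 0.973 (Pearson) and 0.985 (Spearman) with a pseudocount of 0.1, 0.995 and 0.930 with no filter, and 0.992 and 0.989 in the second quantification. The coefficient of variation was 0.0830 with DESeq2 size factors, 0.0849 with spike-in totals, 0.0956 with total counts, 0.0835 with no count filter, 0.0772 at 200 reads or more, 0.0828 without mitochondrially encoded genes and 0.0674 in the second quantification.

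The 210 differing genes became 57 at 200 reads or more (20 higher in animal 2 and 37 in animal 1), 1798 with no fold minimum (1048 and 750), 76 at 4-fold (28 and 48) and 100 with the limit on the assignment spread (38 and 62). They were 211 with DESeq2 size factors, 217 with spike-in totals, 229 with total counts, 244 with no count filter and 170 in the second quantification, which shared 63 with the 210. Of 35 named differing genes all 35 kept direction and call with DESeq2 size factors, 34 with spike-in totals, 33 with total counts and 33 with no count filter. In the second quantification 25 of them were measured, of which 13 kept the call, 8 lost it, and 4 reversed: Hist2h2aa1 (-0.04), Gm20503 (-0.52), Zc3h11a (-0.086) and Gm2274 (-0.46). The 17 shifted lists stayed 17 with DESeq2 size factors and spike-in totals, were 17 in the second quantification (16 shared) and 15 on the log2(TPM + 1) scale (14 shared).

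The median major transcript share was 59.8% in the second quantification and 71.6% at 50 TPM. The Spearman correlation of both quantifications was 0.839 at 10 TPM, with 280 genes over 4-fold, and 0.974 for protein-coding genes alone, with 129. The spike-in share was 0.471% in the second quantification, against 0.608%. Of 71 levels of lists and single genes 57 moved by more than 1 SD in the second quantification, 47 upwards and 10 downwards. These moves include a difference in scale, since small non-coding RNAs took 20.4% of TPM in the first quantification and 0.050% in the second. Depth limits the low lists: neutrophil, liver, lung, thymocyte and Y-linked genes have too few reads for a shift to be measured.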

Other observations

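The comparison of adipocyte with endothelial medians was chosen only after its result was seen, the reading of the word search in Lars2 was changed after its result was seen, and the genes of the next paragraph were chosen after their values were seen.

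Some other protein-coding genes higher in animal 2 had an assignment spread below 10% of their reads. They were picked by name, and no test of a shared function was made. Fn1, which encodes the matrix protein fibronectin, had 3160 and 7197 reads (2.16-fold, 2.07 to 2.25), and Car3, a carbonic anhydrase of fat and muscle, 698 and 1915 reads (2.60-fold, 2.38 to 2.84). Cd5l, a gene of macrophages, had 4 and 37 reads, Retnla 5 and 22, Padi4 10 and 62, the lymphocyte genes Irf4 42 and 98 and Bank1 36 and 85, and Selp, an adhesion receptor of platelets and endothelium, 44 and 113. The choline transporter Slc5a7 had 1 and 25 reads, peripherin, Prph, 2 and 20, Syt1 6 and 24 and Tagln3 7 and 24, while the Schwann cell and nerve list fixed beforehand was at a median log2 ratio of 0.14, inside the range of random lists. Of 37 protein-coding genes of this kind higher in animal 2, 15 had at least 200 reads, and of 11 higher in animal 1 none had.

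Small non-coding RNA genes had a median log2 ratio of -1.08 (100 genes), and 52 of the 138 genes higher in animal 1 were of this kind, 25 of them with an assignment spread below 10%. A loss of short molecules of every kind is argued against by 46 short protein-coding genes of under 400 bases, whose median was -0.021 (95% bootstrap interval -0.08 to 0.01). These genes were not matched to the small RNAs in length, so a loss limited to the shortest molecules is not excluded. A loss that grows as the RNA gets shorter was not seen: length and ratio had a Spearman correlation of -0.118 (-0.328 to 0.0970). Medians were -0.65 for 36 shorter and -0.99 for 34 longer genes. The interval treats the 100 genes as separate, though they had 81 different pairs of counts, so it is too narrow. The longer genes include uncertain Rnu3b copies (61 and 0 reads), so their lower median is not shown to be a larger loss. Reads moved between near-identical copies are argued against by the summed reads, 0.546 of those in animal 1 and 0.723 without 7SL RNA. As 7SL RNA dominates the first sum, the sums by class bear more on this. They were 0.313 for small nuclear, 0.505 for small nucleolar and 0.835 for small Cajal body RNAs. A difference in recovery of structured or protein-bound RNA between the preparations may remain, and no biological explanation was tested, as there is 1 group.

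Adipocyte genes (median log2 ratio 1.2) were higher in animal 2, for which a candidate explanation is tissue attached to the outside of the heart. Yet the mesothelial list, which marks the covering of that surface, did not rise (-0.15, 4 of 6 genes below 0, inside the range of random lists). A lower share of cardiomyocytes would raise other cell types alike. As the only source of the adipocyte rise it is argued against by the adipocyte median, 1.04 above the endothelial one, against a spread of 0.302. The mural (0.25), fibroblast (0.24), macrophage (0.20) and endothelial (0.17) medians rose by similar amounts, with sarcomere at -0.02, while the mesothelial one did not rise. A lower share of cardiomyocytes thus stays open for the lists that rose alike. A list of 9 serosal macrophage genes written before it was looked up had a median of 0.43 over 8 genes, above 99.7% of random lists, which goes with more such cells, although none of the 8 passed the 2-fold test, most, such as Saa3 (6 and 18 reads) and F10 (9 and 23), were low, Rarb with the most reads (648 and 704) was at 0.043 and Wnt2 (30 and 23) at -0.45. A separate list of 12 fat genes had a median of 0.081 over 11 genes, above 95.4% of random lists but inside their central 95%, with Lgals12 (8 and 43 reads) alone past 2-fold, Fasn at 0.46 and Dgat2, which had the most reads (10368 and 9692), at -0.17 (8 of 11 genes above 0), so more fat tissue stays open; heart muscle also expresses several of them. These explanations concern which tissue was sampled, and no biological one was tested, as there is 1 group.

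Lars2 (chromosome 9, 123366927 to 123462666), a mitochondrial leucyl-tRNA synthetase gene, had 3878 and 7901 reads (log2 ratio 0.95, 0.89 to 1.01), and Gm42418 at the ribosomal DNA was at 0.42. A joint rise of mitochondrial tRNA ligases is argued against by 16 other such genes, whose median was -0.034 (-0.06 to 0.02). Residual ribosomal RNA counted in Lars2 would need shared sequence, and its transcripts shared 0 words of 31 bases with Gm42418 or Gm26917. That result was set beforehand to count against this explanation, but the search covered the sequence of these 2 genes alone. They share words with 1 long annotated ribosomal RNA gene, CT010467.1, and the rest of the ribosomal repeat was not searched. Residual ribosomal RNA therefore cannot be told apart from a change in Lars2 itself. Gm26917 was at 0.08 (0.071 to 0.082), apart from Gm42418 at 0.42 (0.41 to 0.44), while CT010467.1, with 57 and 47 reads, was too low to place (-0.35, -0.94 to 0.23).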
